A study of Homo sapiens with 18 samples.

How the data were processed

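Total RNA of 18 samples of DU145, a human prostate cancer cell line, was measured on Illumina expression BeadChips, on which a bead-bound probe reads the abundance of 1 transcript. Per the labels, the cells had been transfected by lipid carrier with 1 of 5 synthetic microRNA mimics at 20 nM or with a mock molecule, and RNA was taken with Trizol and amplified to biotin-labelled cRNA. Each of the 6 groups held 3 arrays. The names miR-205* and miR-221* are older names for the passenger strands now called miR-205-3p and miR-221-5p. The labels do not say whether the 3 samples of a group came from separate cultures or days, so every p-value measures only the spread between these samples, which may be technical.

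The authors deposited a table of probe intensities on a linear scale, not normalized per the file headers, with a column headed as detection p-value beside each intensity. It held 49576 probe lines, of which 773 were empty on every array and 48803 held values. In 6 arrays (mock and miR-875-5p) the deposited detection p-value fell with the intensity of its probe, with Spearman correlations across probes between -0.996 and -0.994. In the other 12 arrays the deposited detection column stood in another line order than the intensities, with correlations between 0.0034 and 0.0078 to them and between 0.897 and 0.93 among those columns. Detection p-values were therefore assigned by rank of intensity within each array, for all arrays alike. In those 12 arrays the deposited values were taken as the complement of a p-value, high where signal is high. On the 6 arrays that could be checked, the calls made this way matched the deposited ones for at least 99.996% of probes. Their correlations all but fixed that match, and it does not check the 12 other arrays or the reading of their values.

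The authors also deposited processed values. Per the submitters' processing notes, lumi was used, with no version given in the sources used here. In that table the 6 columns of mock and miR-875-5p held log2 values that correlated with the array's own log2 intensities at 0.9983 or more, and the other 12 columns equalled the intensities, so those deposited log2 values served only as an alternative for miR-875-5p against mock. The medians of the 6 columns were 7.51, 7.51 and 7.52 for mock replicates 1 to 3 and 7.51, 7.52 and 7.52 for miR-875-5p replicates 1 to 3. Their scale is log2 and genes were not centred. The exact background correction and transformation behind them are not given in the sources used here.

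Intensities were background-corrected by the normexp model with an offset of 16 and quantile-normalized (the neqc method of limma 3.58.1 in R 4.3.3), with the spread of the negative controls inferred from the detection p-values. Probes with detection p below 0.01 on at least 3 arrays were kept, which left 14822. The platform annotation gave 28098 probes with values 1 gene symbol and 13 several, and 20692 had no entry in it. Symbols were brought up to date through the Entrez gene identifier for 28059 probes. Of the kept probes 12718 had a single symbol, and the brightest probe of each gene was used, which gave 9767 genes. Genome positions are not given, since no genome build is named for the probes.

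The depth of an array is its signal over background. The median raw intensity of an array lay between 162.3 and 210.8, and between 12906 and 14231 probes were detected per array, or 26.4% to 29.2% of them. With 3 arrays per group, the number of arrays limits the precision of every value. A gene whose probes were detected on no array of a group has only a bound there. Its fold is given as "at least", the brighter group's mean against the mean of the lowest detected signal of each array of the other group or the probe's own signal where higher. The same bound, from the arrays' signals or lowest detected signals, is given for a named gene detected on only 1 or 2 arrays of a group. No fold is given where both groups were undetected.

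All 18 arrays entered 1 linear model with 6 group means (lmFit and eBayes of limma, 12 residual and 5.09 prior degrees of freedom), with Benjamini-Hochberg adjustment over the 9767 genes and a threshold of 0.05. Every adjusted p of a gene below comes from this limma model, and log2 differences are given as mimic minus reference with their standard error (SE). Each mimic was compared with mock and, so that the mock arrays do not enter, with the mean of the other 4 mimics. The labels place miR-205* and miR-1272 on 1 slide and miR-221* and miR-141 on another, and give none for mock and miR-875-5p, so a slide effect could not be fitted beside the groups. The pairs that share a slide were therefore also compared directly, a choice made after the data were seen.

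Before the data were examined, 32 lists of genes were fixed, along with the tests, the alternatives and the rule for naming genes. Lists were tested with camera in limma, which compares the genes of a list with all other genes, at a preset inter-gene correlation of 0.01, with adjustment over the 32 lists of a comparison. Each was also tested with the correlation estimated from the data, a stricter test, and with fry. The rule named, per comparison with mock, the 8 largest rises and 8 largest falls among genes past the threshold whose 3 mimic arrays all lay on one side of the 3 mock arrays and that were detected on all 3 arrays of at least 1 group. It left out provisional symbols. It added EGFR, HIP1, CDH1, ZEB1 and ZEB2 in every comparison, and for each list described the 2 to 4 members with the largest change among those past the threshold.

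The steps were tested on simulated arrays with 9767 genes, of which 70 changed 1.5-fold, 70 changed 2-fold and 60 changed 4-fold in each mimic. For miR-875-5p against mock the model found 85.7% of genes changed 1.5-fold, 95.7% of those changed 2-fold and all changed 4-fold, with 9 false calls, 4.6% of the calls. For miR-205* against mock it found 75.7%, 97.1% and all of them, with 9 false calls. In the simulated miR-875-5p comparison the 1 list that had been moved was found and no unmoved list was called. The simulated noise was independent between genes and the lists were random, so this does not test lists whose genes are correlated. Alternatives covered the background correction, the scaling, the filter on dim probes, the choice of probe, the arrays in the fit, array weights, the replicate number as a block and each array left out in turn. Tests on 3' UTR seed sites were planned but not run, since no genome or UTR sequence was used here.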

Results

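Messenger RNA levels were measured in DU145 prostate cancer cells after transfection with 1 of 5 synthetic microRNA mimics (miR-875-5p, miR-205*, miR-1272, miR-221* or miR-141) or with a mock molecule, with 3 arrays in each of the 6 groups. A mimic is a short double-stranded RNA that loads the cell with 1 mature microRNA, and the design asks which transcripts each one raises or lowers. Levels are normalized intensities on the log2 scale. Arrays of a group correlated at 0.990 to 0.994 across genes and arrays of different groups at 0.962 to 0.989, and the median SD within a group was 0.125. The first principal component held 27.2% of the variance and the second 21.6%.

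EGFR, HIP1, CDH1, ZEB1 and ZEB2 were fixed in advance as reported targets or markers. EGFR, the epidermal growth factor receptor and a reported target of miR-875-5p, fell with miR-875-5p from 9.98 ± 0.13 in mock to 8.98 ± 0.07 (SD, n = 3), 1.99-fold lower (SE 0.09 on the log2 scale, adjusted p = 1.32e-06). It also fell with miR-1272, by 0.52 (SE 0.09, adjusted p = 0.00036). Its log2 differences were -0.00 with miR-205* (adjusted p = 0.998), 0.00 with miR-221* (adjusted p = 0.985) and 0.25 with miR-141 (adjusted p = 0.0551), none past the threshold. A second detected EGFR probe read -0.78 with miR-875-5p and -0.47 with miR-1272. HIP1, an endocytic adaptor protein that binds clathrin and a reported target of miR-1272, was detected on all 3 mock arrays and on none with miR-1272, at least 2.40-fold lower (adjusted p = 2.69e-08). HIP1 also fell with miR-221*, by 0.56 (adjusted p = 0.00353), and its difference of 0.34 with miR-875-5p did not pass the threshold (adjusted p = 0.0807).

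CDH1, which encodes the epithelial adhesion protein E-cadherin, rose with miR-141 from 8.24 ± 0.13 to 11.62 ± 0.35 (SD, n = 3), a 10.4-fold rise (log2 difference 3.38, SE 0.19, adjusted p = 3.74e-09). It rose 2.89-fold with miR-1272 (adjusted p = 1.79e-05) and 1.72-fold with miR-875-5p (adjusted p = 0.0102). The log2 differences of CDH1 were -0.37 with miR-221* (adjusted p = 0.167) and -0.14 with miR-205* (adjusted p = 0.753). ZEB1, a repressor of CDH1 and a known target of the miR-141 family, was close to background. Its probe was detected on no mock array and on no miR-141 array, so no difference is given. With miR-1272 ZEB1 was detected on 2 of 3 arrays and was at least 1.10-fold higher than in mock (adjusted p = 0.00364). Both probes of ZEB2 were detected on no array, and ZEB2 was not tested. CDH1, HIP1 and ZEB1 each rest on 1 probe.

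**Figure D1:**
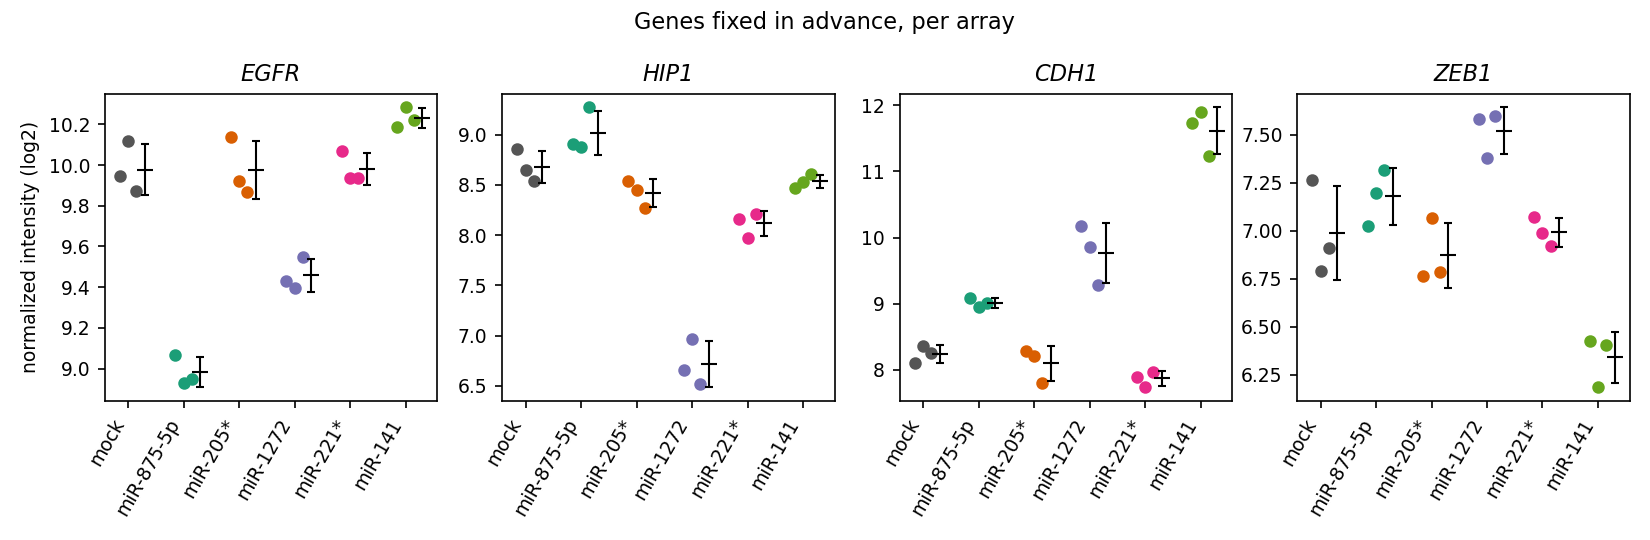
Normalized log2 intensity (vertical axis) of EGFR, HIP1, CDH1 and ZEB1 on each array, by group; points are arrays, and the bar with whiskers is the mean ± SD of 3 arrays. EGFR is lowest with miR-875-5p (mean 8.98), HIP1 with miR-1272 (mean 6.72), and CDH1 is highest with miR-141 (mean 11.62); ZEB1 lies near background throughout.

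Of 9767 genes, 3107 differed from mock with miR-1272, 2999 with miR-221*, 2299 with miR-141, 1769 with miR-875-5p and 513 with miR-205*. Most changes were small. A fitted difference of at least 2-fold was found for 85 genes that rose and 152 that fell with miR-1272, 91 and 101 with miR-221*, 111 and 65 with miR-141, 75 and 61 with miR-875-5p, and 7 and 19 with miR-205*. The balance of rises and falls depended on the scaling of the arrays. By quantile normalization 976 genes rose and 793 fell with miR-875-5p, and by median scaling 536 rose and 727 fell. Median scaling here divided the log2 values of each array by a factor that brought the array medians together. It therefore stretches or shrinks the log2 scale and is not a plain shift. With miR-205* the split was 209 up and 304 down by quantile normalization and 88 and 373 by the median. For miR-221* it was 1342 up and 1657 down against 2508 and 656, and for miR-141 1066 up and 1233 down against 2692 and 355. For miR-1272 it was 1499 up and 1608 down against 1671 and 1220. Between 26.4% and 29.2% of probes were detected on an array, so the median probe lay below detection. Median scaling moved the median log2 difference of all genes to 0.18 with miR-221* and 0.21 with miR-141, from -0.02 with both by quantile normalization. Scaling on the median of the detected probes, added after the data were seen, shifted the log2 values instead. It gave splits of 1373 up and 1565 down for miR-221* and 1011 up and 1303 down for miR-141. These scalings differ both in the operation and in the probes used, and the parts were not told apart.

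**Figure D2:**
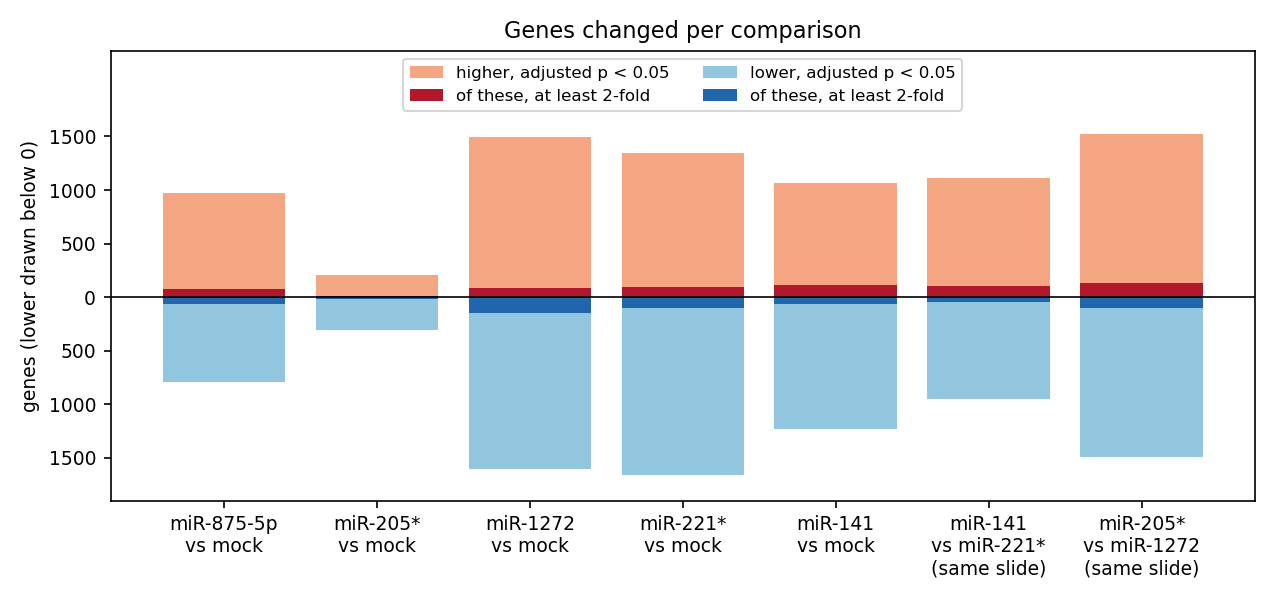
Number of genes with adjusted p below 0.05 (limma) in each comparison, drawn upward where higher and downward where lower in the first-named group; dark bars are those with a fitted change of at least 2-fold. Among the comparisons with mock, fewest genes changed with miR-205* (513) and most with miR-1272 (3107), though by median scaling most changed with miR-221* (3164, against 2891 with miR-1272), and there the balance for miR-1272 (1671 up and 1220 down), miR-221* and miR-141 against mock tips to rises (2508 up and 656 down, 2692 up and 355 down).

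With miR-875-5p, the protein kinase A inhibitor gene PKIA was at least 3.77-fold higher than in mock, where it was not detected (adjusted p = 1.05e-09). SYT11, a synaptotagmin that acts in vesicle traffic, was at least 3.92-fold higher (adjusted p = 4.11e-07), detected on 2 of the 3 mock arrays. CYBRD1, a ferric reductase, rose 3.40-fold (adjusted p = 3.70e-07). ELL2, a transcription elongation factor, was at least 4.78-fold lower and the cytokine gene IL24 at least 3.37-fold lower, neither being detected with the mimic (adjusted p = 3.81e-07 and 5.94e-07). TMX1, a thioredoxin-like protein of the endoplasmic reticulum, fell by 1.69 on the log2 scale from a level of 14.6 (SE 0.10, adjusted p = 1.21e-08).

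Other named rises with miR-875-5p were ARID5B, at least 2.89-fold and detected on 1 mock array, AXIN2, a feedback inhibitor of Wnt signalling, at least 1.39-fold, CPT1C at least 1.37-fold, CYP4F3 at least 1.77-fold and CCDC184 at least 1.20-fold. Other named falls were NFE2L3, a transcription factor of the NRF2 family, and TMEM208, both with a log2 difference of -1.64, FGFBP1, at least 2.89-fold lower and detected on 2 arrays with the mimic, and IMPACT, which was not detected with the mimic. The probe used for BRWD1 fell by 1.80, but its other detected probes read -0.89, 0.26 and 0.34, so its change is uncertain.

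Of 20 measured NF-kB and inflammatory cytokine genes, 12 fell and 2 rose with miR-875-5p (14 and 2 adjusted over the list alone; camera, adjusted p = 3.97e-05; adjusted p = 0.052 with an estimated correlation). IL32 fell by 1.16 on the log2 scale and the chemokine gene CCL20 was at least 1.97-fold lower, whereas IL6, an inflammatory cytokine, rose by a log2 difference of 1.42 (adjusted p = 0.000558). LTB also fell but was undetected on all arrays with the mimic and on 2 of 3 mock arrays. Of 19 MAPK-responsive genes, which are induced by or feed back on the kinase cascade below growth factor receptors, 8 fell and 1 rose (8 and 2 adjusted over the list alone; camera, adjusted p = 0.0298; adjusted p = 0.429 with an estimated correlation). The feedback inhibitor SPRY4 was at least 2.01-fold lower, and FOSL1, a subunit of the AP-1 transcription factor, fell by 1.03. Without mock replicate 1 or 2 that list was not called (adjusted p = 0.0568 and 0.136).

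Of 19 cholesterol synthesis genes, 5 rose with miR-875-5p (9 adjusted over the list alone; camera, adjusted p = 0.00102; adjusted p = 0.266 with an estimated correlation). The largest rises among them, TM7SF2 at 0.74 and MVD at 0.61, were not called in several fits that left out 1 array. TM7SF2 lost its call without mock replicate 1 or 2 or miR-875-5p replicate 2 or 3 (adjusted p = 0.0515 to 0.0931), and MVD without mock replicate 1 or 2 or miR-875-5p replicate 3 (adjusted p = 0.0571 to 0.075). Of the other rises, HSD17B7 lost its call in 5 fits that left out 1 array (adjusted p = 0.0583 to 0.137) and MSMO1 in 1 (adjusted p = 0.0599). Of 36 G1/S and DNA replication genes, 6 fell, the same number as adjusted over the list alone (camera, adjusted p = 0.0298; adjusted p = 0.527 with an estimated correlation). Among them the replicative helicase subunit MCM4 fell by 0.67 and GINS2 by 0.47. Without mock replicate 1, mock replicate 2 or miR-875-5p replicate 2 the list was not called (adjusted p = 0.111, 0.0807 and 0.0645). The count of genes changed was 1165 without mock replicate 1 and 1155 with only the 2 groups in the fit.

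The mimic miR-205* changed the fewest genes. PKIA was at least 2.20-fold higher than in mock, the interstitial collagenase gene MMP1 at least 1.73-fold and the hyaluronan-binding protein gene CEMIP at least 1.27-fold (adjusted p = 1.77e-07, 0.00265 and 4.65e-05). SNRPC, a component of the U1 splicing particle, rose 2.30-fold (SE 0.11 on the log2 scale, adjusted p = 2.51e-05). AKR1C2, an aldo-keto reductase that metabolizes steroids, fell by 1.36 and its relative AKR1C4 by 1.14 (adjusted p = 4.65e-05 and 5.76e-05). The AKR1C genes are near-identical copies whose probes may share signal, so the member that changed is uncertain. The linker histone gene H1-2 fell by 1.06 (adjusted p = 6.03e-05).

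Further named rises with miR-205* were NARF (2.33-fold), RP2 (at least 2.03-fold, detected on 1 mock array), ERLIN2 (2.06-fold) and ARPC4, an actin-nucleating complex subunit (1.94-fold). The 2 other detected probes of ERLIN2 read log2 differences of 0.33 and 0.49. Further named falls were CLIC3 (at least 1.16-fold), the carboxypeptidase gene CPA4 (not detected with the mimic), PDLIM2 (at least 1.15-fold), ATL1 (at least 1.64-fold) and CTNNBIP1, an inhibitor of beta-catenin, with a log2 difference of -1.13. Against the mean of the other mimics, CEMIP alone of the named rises was higher (limma adjusted p = 0.00136). PKIA was lower there (-0.36, adjusted p = 0.0296). MMP1, NARF, RP2, SNRPC, ERLIN2 and ARPC4 did not pass the threshold (adjusted p = 0.202 to 0.635). All named falls but AKR1C2 and PDLIM2 were also lower (adjusted p at most 0.00192). Of the 513 genes called against mock, 191 (37.2%) were called in the same direction there and 18 in the opposite.

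Replication-dependent histone genes, which supply nucleosomes in S phase, fell together with miR-205*: 9 of 13 fell (11 fell and 1 rose adjusted over the list alone; camera, adjusted p = 3.9e-12; adjusted p = 0.0128 with an estimated correlation). H2BC4 was at least 1.85-fold lower, detected on 1 of 3 arrays with the mimic. Histone genes are also near-identical copies, so single members are uncertain. Against the other 4 mimics 4 of 13 were lower and 1 higher, and the list was not called with an estimated correlation (adjusted p = 0.231). Of 21 NRF2 antioxidant genes, 4 fell, as many as adjusted over the list alone (camera, adjusted p = 0.00277; adjusted p = 0.0394 with an estimated correlation), led by AKR1C2 and by AKR1C3, which fell by 0.97. The other 2 were often not called without 1 array: AKR1B10 without mock replicate 1 or 2 or miR-205* replicate 2 or 3 (adjusted p = 0.0637 to 0.135), and ABCC3 without any 1 array except mock replicate 1 (adjusted p = 0.0863 to 0.144). Of 29 interferon-stimulated genes, 4 fell (7 adjusted over the list alone; camera, adjusted p = 0.000283; adjusted p = 0.128 with an estimated correlation). Among them IFITM3, an inhibitor of virus entry, was at least 1.27-fold lower, GBP2 fell by 0.73 and IFIT1 by 0.61. IFITM3 was not called without mock replicate 2 or 3 or miR-205* replicate 1 or 3 (adjusted p = 0.0708 to 0.0954), nor GBP2 without any 1 array except mock replicate 1 (adjusted p = 0.0631 to 0.139).

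Of 20 NF-kB and inflammatory cytokine genes, 6 fell and 1 rose with miR-205* (8 and 3 adjusted over the list alone; camera, adjusted p = 0.0103; adjusted p = 0.153 with an estimated correlation). Without miR-205* replicate 2 that list was not called (adjusted p = 0.0501). TNFAIP2 fell by 0.66, while the larger falls of CCL5 and LTB were on probes near or below background and that of IL6, 0.94, was called in only 1 of 6 fits that left out an array (adjusted p = 0.0521 to 0.127 in the others). Of 19 MAPK-responsive genes, 3 rose (7 adjusted over the list alone; camera, adjusted p = 0.00277; adjusted p = 0.128 with an estimated correlation), among them IER3 by a log2 difference of 0.63 and the feedback inhibitor SPRY1 by 0.60. IER3 was not called with only the 2 groups in the fit (adjusted p = 0.059). Of 30 glycolysis and hypoxia genes, 4 rose and 1 fell (7 and 1 adjusted over the list alone; camera, adjusted p = 0.0138; adjusted p = 0.246 with an estimated correlation). ANGPTL4, an inhibitor of lipoprotein lipase, rose by 0.73 and the peptide hormone gene ADM fell by 0.99. Among the other rises, ENO2 and VEGFA each lost the call in 5 fits that left out 1 array (limma adjusted p = 0.0659 to 0.134 and 0.0524 to 0.136). The G1/S and DNA replication list was called upward (camera, adjusted p = 0.00287; adjusted p = 0.246 with an estimated correlation) although limma called 0 of its 36 genes, over all genes or adjusted over the list alone, and 8 lay above mock at an unadjusted p below 0.05. Its largest log2 difference was 0.42, for RRM2 (adjusted p = 0.129). The count of genes changed was 200 with only the 2 groups in the fit, 316 without mock replicate 2, 295 without miR-205* replicate 1 and 332 without replicate 3.

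With miR-1272, MYO1D, an unconventional myosin, was at least 2.72-fold lower and not detected with the mimic (adjusted p = 4.66e-09). STRADB, a pseudokinase partner of the kinase LKB1, was at least 5.92-fold lower and detected on 2 of 3 arrays with the mimic (adjusted p = 1.84e-07). KCTD14 fell by 2.21 (SE 0.12), SNX10, a sorting nexin of endosomes, changed by -2.07 (SE 0.12) and ANAPC11, the RING subunit of the anaphase-promoting complex, by -1.87 (SE 0.11), with adjusted p of 4.66e-09, 5.47e-09 and 8.46e-09. A second ANAPC11 probe, detected on all 18 arrays, read a smaller fall, at -1.05. CYP4F3, a cytochrome that degrades leukotriene B4, was at least 2.87-fold higher and PKIA at least 2.69-fold (adjusted p = 1.68e-05 and 5.47e-09). The adaptor gene PAG1 rose 3.64-fold and the organic anion transporter gene SLCO2B1 was at least 3.20-fold higher, the latter detected on 2 mock arrays (adjusted p = 1.60e-06 and 5.20e-06).

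MXD1, an antagonist of MYC, was at least 2.48-fold higher with miR-1272 and detected on 1 mock array, SPOPL was at least 1.74-fold higher and FCGBP at least 1.47-fold. ERLIN2 rose 3.03-fold by the probe used, but its 2 other detected probes read -0.13 and 0.11. GKN2 was at least 2.69-fold lower. LHX6 was at least 3.20-fold lower by the probe used, whereas a second probe, detected on all 18 arrays, read 0.05, so both ERLIN2 and LHX6 are uncertain in this comparison.

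Of 19 cholesterol synthesis genes, 13 rose with miR-1272 (14 adjusted over the list alone; camera, adjusted p = 6.43e-06; adjusted p = 0.0568 with an estimated correlation), among them the sterol oxidase MSMO1 by a log2 difference of 1.19 and INSIG1, a sterol-regulated anchor of the SREBP pathway, by 0.95. Of 21 NRF2 antioxidant genes, 11 rose (13 adjusted over the list alone; camera, adjusted p = 0.000331; adjusted p = 0.0218 with an estimated correlation), led by AKR1B10 at 1.10, SRXN1 at 0.74 and the heme oxygenase gene HMOX1 at 0.70. Of 29 interferon-stimulated genes, 11 rose and 3 fell (13 and 3 adjusted over the list alone; camera, adjusted p = 0.00539; adjusted p = 0.36 with an estimated correlation). DDX60 was at least 1.61-fold higher, and IFIT3 and OASL rose by 1.28 each. Of 36 G1/S and DNA replication genes, 15 fell and 1 rose (17 and 1 adjusted over the list alone; camera, adjusted p = 0.000401; adjusted p = 0.292 with an estimated correlation), and MCM4 fell by 1.36 (SE 0.10, adjusted p = 6.22e-08).

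With miR-221*, PKIA was at least 2.56-fold higher and MMP1 at least 3.04-fold (adjusted p = 5.17e-09 and 4.78e-06). STC1, a secreted glycoprotein hormone, rose 4.45-fold from 10.12 ± 0.03 to 12.27 ± 0.11 (SD, n = 3; adjusted p = 1.30e-10), ANGPTL4 3.35-fold and the adhesion receptor gene ADGRG1 3.17-fold (adjusted p = 3.61e-08 and 1.04e-08). AKR1C2 was at least 4.44-fold lower and not detected with the mimic (adjusted p = 3.05e-09), while AKR1C3 fell by 1.68 and AKR1C4 by 1.63. UCP2, a mitochondrial carrier, fell by 2.11 (SE 0.12, adjusted p = 3.10e-09) and the carrier gene SLC16A9 was at least 3.16-fold lower. IL6 fell by 1.71 and STAT4, a transcription factor of cytokine signalling, by 1.51 (adjusted p = 6.54e-05 and 3.40e-07).

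Further named rises with miR-221* were BBOF1 (at least 3.40-fold, detected on 1 mock array), RRAD, a small GTPase (at least 1.59-fold), and G0S2, an inhibitor of the triglyceride lipase ATGL (3.22-fold). STRADB fell by 1.57. Of 19 MAPK-responsive genes, 9 rose and 1 fell (9 and 2 adjusted over the list alone; camera, adjusted p = 0.0034; adjusted p = 0.122 with an estimated correlation). The feedback inhibitor SPRY4 rose by 1.66 on the log2 scale and the ERK phosphatase DUSP6 by 1.40. Of 29 interferon-stimulated genes, 17 fell and 1 rose, as adjusted over the list alone (camera, adjusted p = 0.00047; adjusted p = 0.122 with an estimated correlation), with IFIT1 down by a log2 difference of -1.44 and IFIT2 by -1.28. Of 20 genes of the TGF-beta pathway, 8 fell and 1 rose, again as adjusted over the list alone (camera, adjusted p = 0.0248; adjusted p = 0.122 with an estimated correlation), among them ID3 and ID1, inhibitors of basic helix-loop-helix factors, which fell 2.00-fold and 1.93-fold. Of 22 epithelial junction and keratin genes, 7 fell and 1 rose (9 and 2 adjusted over the list alone; camera, adjusted p = 0.0284; adjusted p = 0.394 with an estimated correlation). The tight junction protein cingulin, CGN, fell by 1.03, the desmosomal cadherin DSC2 by 0.88, and CLDN1 rose by 0.86. Without miR-221* replicate 2 that list was not called (adjusted p = 0.0716).

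Of 21 NRF2 antioxidant genes, 7 fell with miR-221*, as many as adjusted over the list alone (camera, adjusted p = 0.0248; adjusted p = 0.122 with an estimated correlation), with AKR1C2 and AKR1C3 in front. By median scaling that list was not called (adjusted p = 0.0592). Of 36 G1/S genes 14 fell and 1 rose (16 and 2 adjusted over the list alone), with a mean log2 difference of -0.17 that turned to 0.05 by median scaling and was -0.12 relative to the median of all genes there (camera, adjusted p = 0.0256; adjusted p = 0.357 with an estimated correlation). The uracil glycosylase UNG fell by 0.72 and GINS3 by 0.55. Of 44 G2/M genes 13 fell and 1 rose, as adjusted over the list alone, with a mean of -0.15 that turned to 0.08 by median scaling, -0.10 relative to that median (camera, adjusted p = 0.0248; adjusted p = 0.357 with an estimated correlation). The kinetochore protein CENPF fell by 0.69 and cyclin A2, CCNA2, by 0.62. The G1/S list was not called without mock replicate 1 (adjusted p = 0.059), nor the G2/M list without mock replicate 2 (adjusted p = 0.0531). Of 19 cholesterol synthesis genes 6 rose, as many as adjusted over the list alone (camera, adjusted p = 0.0284; adjusted p = 0.357 with an estimated correlation), among them IDI1 by 0.93 and LPIN1 by 0.91. That list was not called without mock replicate 1, mock replicate 2 or miR-221* replicate 1 (adjusted p = 0.059, 0.0531 and 0.0761).

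With miR-141, epithelial genes rose. Besides CDH1, the claudin gene CLDN7 was at least 4.40-fold higher, SPINT1, an inhibitor of the matriptase protease, at least 3.75-fold, and MARVELD3, a tight junction protein, at least 2.28-fold (adjusted p = 2.00e-08, 2.97e-08 and 2.43e-10). LAD1, an anchoring filament protein, was at least 4.21-fold higher and detected on 1 mock array (adjusted p = 2.12e-08). The collagen receptor integrin ITGA2 rose 6.82-fold, from 9.51 ± 0.04 to 12.28 ± 0.22 (SD, n = 3; adjusted p = 1.85e-11). Of 22 measured epithelial junction and keratin genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone; camera, adjusted p = 5.06e-13; adjusted p = 0.0119 with an estimated correlation).

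ANGPTL4 rose 5.90-fold with miR-141 and MMP1 was at least 3.82-fold higher (adjusted p = 2.43e-10 and 1.03e-06). AKR1C2 fell by 2.18, UCP2 by 1.75, IL6 by 1.61 and KCTD20 by 1.54, with adjusted p of 1.81e-08, 1.81e-08, 0.000149 and 1.81e-08. PPT2, a lysosomal thioesterase, was at least 2.64-fold lower (adjusted p = 6.99e-07). Of 13 replication-dependent histone genes, 12 fell and 1 rose, as adjusted over the list alone (camera, adjusted p = 4.81e-12; adjusted p = 0.00731 with an estimated correlation). H3C10 was at least 2.34-fold lower, H2BC21 fell by 1.58 and H4C8 2.83-fold.

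Of 30 glycolysis and hypoxia genes, 15 rose and 1 fell with miR-141 (16 and 1 adjusted over the list alone; camera, adjusted p = 4.67e-08; adjusted p = 0.0113 with an estimated correlation). The hexokinase HK2 rose by a log2 difference of 2.21, PFKFB4, which makes an activator of phosphofructokinase, by 1.91, and NDRG1 by 1.39. Of 19 MAPK-responsive genes, 11 rose and 1 fell (11 and 2 adjusted over the list alone; camera, adjusted p = 1.36e-05; adjusted p = 0.0174 with an estimated correlation), with DUSP6 up by 1.73 and SPRY1 by 1.40. Of 21 NRF2 antioxidant genes, 10 fell and 1 rose (11 and 1 adjusted over the list alone; camera, adjusted p = 1.36e-05; adjusted p = 0.00731 with an estimated correlation), HMOX1 among them with a log2 difference of -1.04. Of 19 cholesterol synthesis genes, 8 rose (9 adjusted over the list alone; camera, adjusted p = 5.45e-05; adjusted p = 0.052 with an estimated correlation), led by LPIN1 at 1.17 and MSMO1 at 0.81.

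Of 13 measured genes reported as targets of miR-141 or its relative miR-200a, 6 fell and 1 rose with miR-141, as adjusted over the list alone (camera, adjusted p = 0.0208; adjusted p = 0.146 with an estimated correlation). Among the 6 was ZEB1, whose probe was detected on no array of either group, so its call is floor signal. The list was not tested without it. The growth factor gene TGFB2 fell by 0.93 and the phosphatase gene PHLPP2 by 0.83, while CTNNB1, which encodes beta-catenin, rose by 0.70. Of 22 basement membrane and integrin genes, 6 rose and 3 fell (9 and 3 adjusted over the list alone; camera, adjusted p = 0.0296; adjusted p = 0.146 with an estimated correlation), with the integrin ITGB4 up by 1.16 and the laminin chain LAMB3 by 1.08. Of 29 unfolded protein response and amino acid stress genes, 5 rose and 2 fell, as adjusted over the list alone (camera, adjusted p = 0.025; adjusted p = 0.473 with an estimated correlation), with DDIT4 up by 1.15 and TRIB3 by 0.72. That list was not called without miR-141 replicate 1 (adjusted p = 0.13), nor with scaling on the detected probes (adjusted p = 0.0553). Of 44 G2/M genes, 9 fell (8 adjusted over the list alone; camera, adjusted p = 0.0296; adjusted p = 0.331 with an estimated correlation), with a mean log2 difference of -0.12 that turned to 0.11 by median scaling and was -0.10 relative to the median of all genes there. CDC25B, a phosphatase that activates CDK1, fell by 0.67 and CENPF by 0.57, the latter not called by median scaling (adjusted p = 0.0839). The G2/M list was not called without mock replicate 2, miR-141 replicate 1 or miR-141 replicate 2 (adjusted p = 0.101, 0.0733 and 0.0716).

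**Figure D3:**
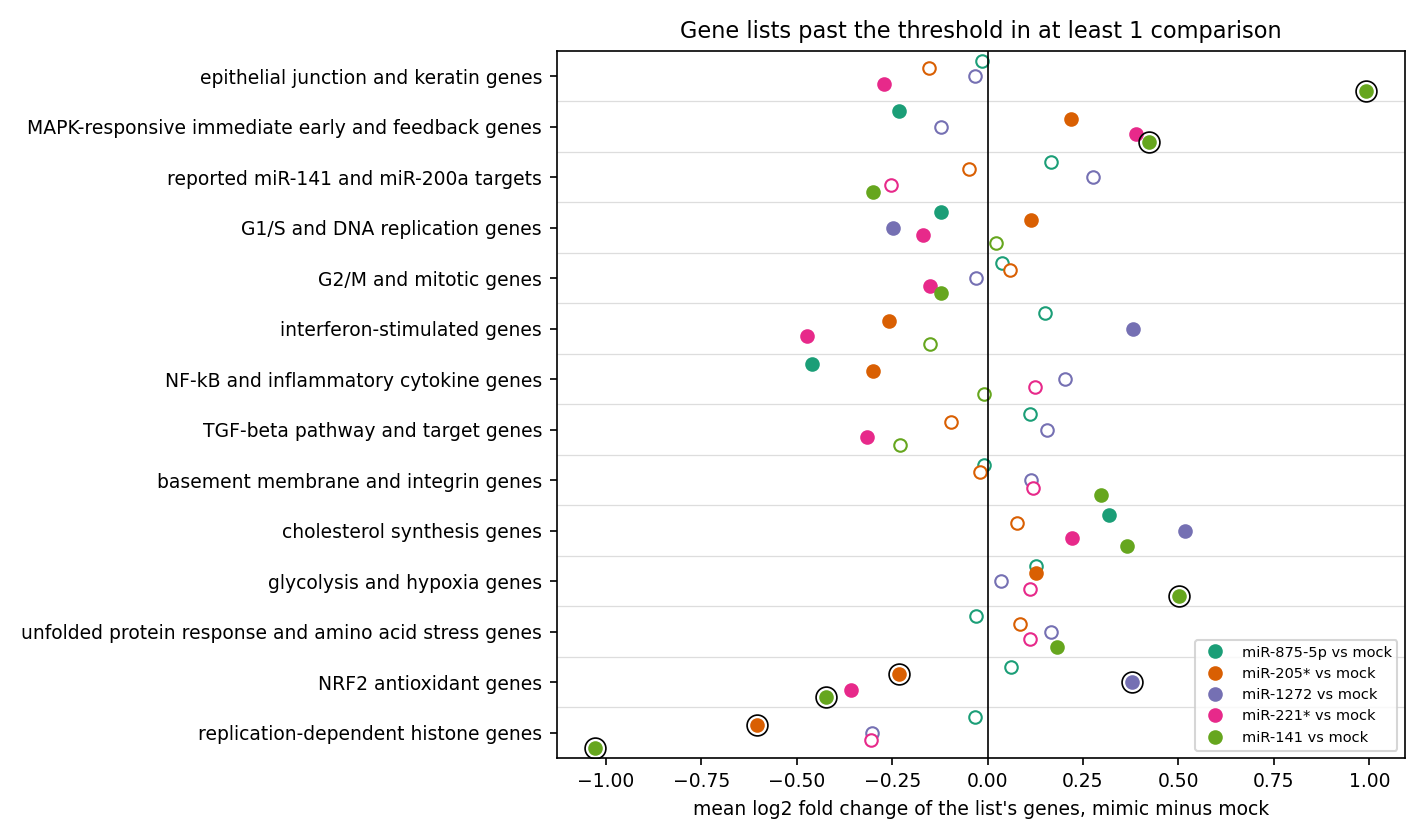
Mean log2 difference from mock (horizontal axis) of the genes of each list that passed the threshold in at least 1 comparison, 1 point per mimic; filled points have a camera adjusted p below 0.05, open points do not, and a black ring marks those also past it with an estimated correlation. Epithelial genes stand at 0.99 and histone genes at -1.03 with miR-141; the means of G1/S genes with miR-221* and of G2/M genes with miR-221* and miR-141 turn positive by median scaling, and relative to the median of all genes there they are -0.12, -0.10 and -0.10.

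Of the 32 lists, 18 passed the threshold in no comparison with mock, and of the 33 list results that passed, 8 also did so with an estimated correlation. The lists of other cell types stayed below the threshold in the comparisons with mock. The lowest adjusted p by camera was 0.321 for 8 measured genes of luminal prostate cells, 0.189 for 4 neuroendocrine genes, 0.265 for 2 fibroblast genes and 0.167 for 3 leukocyte and endothelial genes.

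Set against the mean of the other 4 mimics, where mock does not enter, miR-875-5p differed in 3360 genes (1980 higher and 1380 lower), miR-205* in 1668 (802 and 866), miR-1272 in 3973 (2007 and 1966), miR-221* in 3344 (1497 and 1847) and miR-141 in 2926 (1412 and 1514). By median scaling the splits were 937 and 3073 for miR-875-5p, 121 and 2524 for miR-205*, 2911 and 815 for miR-221*, and 3263 and 436 for miR-141, where it moved the median of all genes to -0.15, -0.17, 0.15 and 0.18. The count for miR-205* was 889, 981 and 943 without its replicates 1, 2 and 3. EGFR was lower with miR-875-5p than with the other mimics by a log2 difference of -0.93 (adjusted p = 5.98e-08), HIP1 was lower with miR-1272, where no array detected it (adjusted p = 1.75e-09), and CDH1 was higher with miR-141 by 2.93 (adjusted p = 5.88e-10).

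The labels put miR-141 and miR-221* on one slide, and 2056 genes differed between them, 1108 higher and 948 lower with miR-141 (1043 and 587 by median scaling). CDH1 was 13.5-fold higher with miR-141 (adjusted p = 1.16e-09) and CLDN7 at least 4.20-fold. Epithelial genes were higher in 19 of 22, as adjusted over the list alone (camera, adjusted p = 1.82e-19; adjusted p = 0.00973 with an estimated correlation). Glycolysis and hypoxia genes were higher in 16 of 30 (17 higher and 1 lower adjusted over the list alone; camera, adjusted p = 3.19e-07; adjusted p = 0.0191 with an estimated correlation) and histone genes lower in 9 of 13 (10 adjusted over the list alone; camera, adjusted p = 1.63e-08; adjusted p = 0.0191 with an estimated correlation). Interferon-stimulated genes were higher in 10 of 29 (11 adjusted over the list alone; camera, adjusted p = 0.000371; adjusted p = 0.125 with an estimated correlation). G1/S genes were higher in 11 of 36 and lower in 2 (16 and 2 adjusted over the list alone; camera, adjusted p = 0.0011; adjusted p = 0.188 with an estimated correlation), UNG by 0.87.

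On the other slide, 3016 genes differed between miR-205* and miR-1272, 1520 higher and 1496 lower with miR-205* (866 and 2199 by median scaling, where the median of all genes was -0.13). NRF2 antioxidant genes were lower with miR-205* in 15 of 21, as adjusted over the list alone (camera, adjusted p = 1.56e-07; adjusted p = 0.00168 with an estimated correlation), AKR1B10 by a log2 difference of -1.57. The other lists called between them lost the call with an estimated correlation. Interferon-stimulated genes were lower in 17 of 29 and higher in 2 (18 and 3 adjusted over the list alone; camera, adjusted p = 2.04e-06; adjusted p = 0.0565 with an estimated correlation), IFIT3 by -1.78. G1/S genes were higher in 20 of 36 (24 adjusted over the list alone; camera, adjusted p = 1.11e-07; adjusted p = 0.0565 with an estimated correlation), MCM4 2.83-fold. Cholesterol synthesis genes were lower in 12 of 19 (13 lower and 1 higher adjusted over the list alone; camera, adjusted p = 6.88e-05; adjusted p = 0.0595 with an estimated correlation) and NF-kB genes in 12 of 20 with 1 higher (12 and 2 adjusted over the list alone; camera, adjusted p = 0.00115; adjusted p = 0.0595 with an estimated correlation). The lists of TGF-beta genes, of reported miR-141 targets and of histone genes were also called lower, with estimated-correlation adjusted p of 0.0845, 0.114 and 0.32.

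The comparisons with mock overlapped. In all 5 of them 62 genes rose and 17 fell. Simulated unchanged groups with shared, also simulated, mock arrays call almost no gene. Their highest count of 0 such genes in 100 runs was therefore fixed in advance and is no yardstick. Independent lists of these sizes would share 0.05 and 0.09, a value that leaves out the shared mock arrays. Of the other groups, each with its own mimic, 215 genes were lower and 251 higher with miR-875-5p than in all 5 others, 522 and 343 with miR-1272, 295 and 155 with miR-221*, 184 and 146 with miR-141, and 24 and 3 with miR-205*. PKIA was detected on no mock array and was at least 2.20- to 3.77-fold higher in the 5 comparisons. RP2 was at least 2.03- to 2.45-fold higher, and SNRPC rose by 0.94 to 1.22 on the log2 scale. By count, the largest overlap of 2 mimics was that of miR-221* and miR-141, the pair on 1 slide. They had 560 genes higher in both and 603 lower in both, against 146.5 and 209.2 for independent lists, and 90 in opposite directions. Every pair shared more genes than independent lists would. Relative to such lists miR-205* and miR-141, on different slides, shared more, with 131 rises against 22.8 and 157 falls against 38.4. Their log2 differences correlated at 0.563 across genes, where simulated unchanged groups with shared mock arrays gave 0.503. Every other pair of mimics lay below its simulated value, at 0.133 to 0.413, so that correlation is no yardstick for changed groups. The covariance of miR-221* and miR-141 was 0.0769 against a simulated 0.0095. It lay above the simulated value in every pair, by 0.0059 (miR-875-5p and miR-141) to 0.0674 (miR-221* and miR-141). Genes are not independent replicates, and the 3 mock arrays were not split between the 2 mimics. The simulated covariance already holds shared mock arrays, but with noise drawn independently for each gene. Part of the excess may therefore still come from the shared controls. AKR1C2, UCP2 and IL6 fell and MMP1, ANGPTL4 and ITGA2 rose with both, but not with these alone. ANGPTL4 and ITGA2 rose in all 5 comparisons. AKR1C2, UCP2, MMP1 and IL6 also changed in the same direction with miR-205*, though IL6 lost that call in most fits that left out 1 array. UCP2 also fell with miR-1272. Among 32915 probes detected on no array, 127 were called between miR-221* and mock, 64 between miR-141 and mock, 27 with miR-1272 and 20 with miR-875-5p. The contrast between the slides called 802 of these probes, while the pairings of the same groups across slides called 17 and 27.

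**Figure D4:**
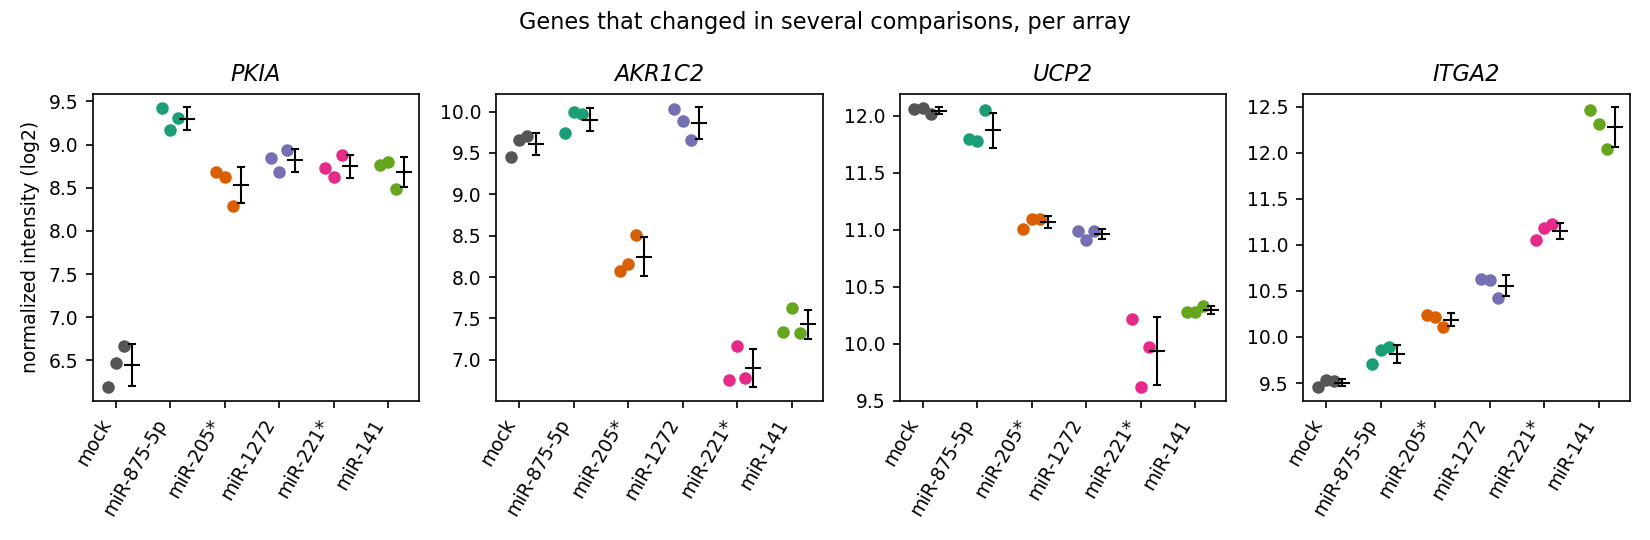
Normalized log2 intensity (vertical axis) of PKIA, AKR1C2, UCP2 and ITGA2 on each array, by group; points are arrays, and the bar with whiskers is the mean ± SD of 3 arrays. PKIA is lower in mock (mean 6.44, not detected) than in every mimic group (means 8.53 to 9.30), while AKR1C2 and UCP2 are lowest with miR-221* (means 6.90 and 9.94) and ITGA2 is highest with miR-141 (mean 12.28).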

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

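The tests of a deviating mock array, of other probes and of shared mock arrays were chosen only after the results were seen. So were those of CDH1 against miR-205* and among epithelial genes. The relabelling of arrays and the tests of hybridisation, of the slide and of the number of CDH1 probes were fixed beforehand. The comparisons between mimics of a slide, which part of these use, had themselves been chosen after the data were seen.

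Of 2104 detected probes that carry no gene name here and enter no comparison of the report, limma called 273 between miR-875-5p and mock, 72 with miR-205*, 409 with miR-1272, 487 with miR-221* and 409 with miR-141. These shares of 13%, 3.4%, 19.4%, 23.1% and 19.4% lie below those of the tested genes in the same comparisons (18.1%, 5.3%, 31.8%, 30.7% and 23.5%). The probes are given as signal in data outside the gene analysis, and their transcripts were not identified.

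For the comparisons with mock and within a slide, 6 arrays make 10 splits, too few for a share under 0.05. The real split alone, 1 of 10, reached its count in each: 1769, 513, 3107, 2999 and 2299 genes against mock for miR-875-5p, miR-205*, miR-1272, miR-221* and miR-141, and 2056 and 3016 between the mimics of a slide. The highest count of another split was 1 for miR-205* against mock and for miR-205* against miR-1272, and 0 by limma in the other 5 comparisons. Against the other 4 mimics, 1 of 100 relabellings of the 15 mimic arrays, the real one, reached the count. A relabelling mixes the arrays of all 5 mimics, so this argues only against a random grouping of the 15 arrays as a whole. It does not test the count of each mimic, and it cannot speak for separate cultures if the 3 samples of a group are technical. The real counts and the highest of the others were 3360 and 2483 for miR-875-5p, 1668 and 1199 for miR-205*, 3973 and 1437 for miR-1272, 3344 and 9 for miR-221*, and 2926 and 2 for miR-141.

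In all 5 comparisons with mock, 62 genes rose and 17 fell, PKIA foremost. At least 92.7% of the median difference stayed when any 1 mock array was left out, but this cannot decide on a single deviating mock array. These genes were chosen by calls against all 3 mock arrays. A deviation of 1 array also widens the spread, so genes resting on it would rarely have been called. The signal of a single probe per gene is argued against only for genes with another detected probe, since 82.8% of 29 such probes had the same direction. There were 79 genes in all, so most could not be checked this way. A hybridisation difference of the mock arrays cannot be told apart, because the labels give mock no slide: among 32915 probes detected on no array, 3 were called between mock and the mimics against 78 between miR-875-5p and the other groups, and probes at the floor cannot speak for brighter ones. An effect of the mock molecule itself and a response common to the 5 mimics both stay open and were not tested.

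The mimics miR-221* and miR-141 shared 1163 genes called in the same direction against mock. Shared mock arrays as the whole origin are argued against, since genes chosen without 1 replicate of the 2 mimics kept their direction on the left-out arrays against the mimics of the first slide, without mock, in at least 86.5% of rises or falls, where noise in mock alone would give 50%. Slide 2 as the whole source cannot be told apart. The share of these genes called between the 2 mimics on that slide was 16.2%, between the bounds of 5% and 20% set beforehand. Genes chosen for moving the same way in both mimics would differ less between them, and over all 9767 genes the share was 21.05%. An effect of each mimic on top of the slide could also make such genes differ, so the bounds do not settle it. For slide 2 as part of the source, 802 of 32915 probes detected on no array were called between the slides. The 2 other pairings of the 4 groups called 17 and 27. The higher count is what the prediction set beforehand asked of a slide effect. That contrast also parts miR-221* and miR-141 from the other 2 mimics, and an undetected probe can still hold signal. Among the 9767 tested genes it called 3981, against 2077 and 3088. A technical part and a shared effect of the 2 mimics therefore cannot be told apart.

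CDH1 was higher with miR-1272 than with mock. The slide or the mock arrays as its origin are argued against, since CDH1 was higher by 1.67 on the log2 scale with miR-1272 than with miR-205* on the same slide. The same de-repression of epithelial genes as with miR-141 is also argued against, since of 4 other epithelial genes detected in mock that rose at least 2-fold with miR-141, CRB3, EPCAM and MAL2 fell with miR-1272 and CDH3 rose by 1.04 (median -0.608, SD 0.837). The signal of a single probe cannot be told apart, because the array holds 1 CDH1 probe. A de-repression of CDH1 and CDH3 alone and any other effect of miR-1272 on CDH1 stay open and were not tested.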

How the results depend on the processing

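The tests with scaling on the median of the detected probes, with detection taken from 6 arrays and between mimics of a slide were chosen only after the data were seen. Of 216 results for named genes, 180 kept their direction and side of the threshold in every alternative run. Of 33 list results, 8 did so, and the other 25 lost the call with an estimated correlation. Some named genes gained a call by limma. EGFR with miR-141 did so by median scaling (0.49, adjusted p = 0.00609, where the median of all genes was 0.21). It also did with detection on all 18 arrays (adjusted p = 0.0492) and without mock replicate 2 (adjusted p = 0.0309). CDH1 with miR-221* did so with only the 2 groups in the fit (-0.37, adjusted p = 0.0408). A block for slide was not run, since the labels give none for mock and miR-875-5p, and seed-site tests were not run. The cause of the changes below was not tested, except that a fit of 2 groups or without 1 array holds fewer arrays.

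With only the 2 groups in the fit, 1155 genes differed for miR-875-5p and 200 for miR-205* against mock. Median scaling gave 2645 for miR-205* against the other 4 mimics. Without 1 array the counts were 1165 to 1529 (miR-875-5p against mock), 295 to 378 (miR-205* against mock) and 889 to 1648 (miR-205* against the other 4 mimics). The replicate block, whose numbers do not pair the arrays, gave 1722, 493, 3104, 2934 and 2281 genes against mock for miR-875-5p, miR-205*, miR-1272, miR-221* and miR-141.

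Signs that turned belong to log2 differences near 0, save LHX6 with miR-1272, which read 0.0516 with detection on all 18 arrays because another probe was then used. EGFR with miR-205* read 0.1137 as the mean of its probes and -0.0825 to 0.0683 without 1 array. EGFR with miR-221* read -0.0270 as the mean of its probes, -0.0182 with array weights and -0.0499 to 0.0730 without 1 array. Without 1 array CDH1 with miR-205* read -0.2317 to 0.0130. The ZEB1 probe was undetected in both groups, so its values are floor signal and no folds: -0.2154 to 0.0212 without 1 array with miR-205*, and with miR-221* 0.0000 without background correction, -0.0494 with scaling on detected probes, -0.0092 with array weights and -0.0945 to 0.1422 without 1 array. By median scaling HIP1 with miR-141 read 0.0913, and the list means were 0.0538 (G1/S) and 0.0789 (G2/M) with miR-221* and 0.1105 (G2/M) with miR-141. Between 26.4% and 29.2% of probes exceeded background per array, which limits what can be said of transcripts such as ZEB1 and ZEB2.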

Other observations

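The list tests against the other 4 mimics below were chosen only after the results were seen. Each mimic was set against the mean of the other 4, without mock; these contrasts sum to 0 for every gene, so a list higher in one mimic is lower in others by construction. MAPK-responsive genes were lower with miR-875-5p in 12 of 19 and higher in 3, as adjusted over the list alone (camera, adjusted p = 1.46e-05; adjusted p = 0.0331 with an estimated correlation), DUSP5 by a log2 difference of -1.48, while FOS was higher by 1.24. With miR-141 they were higher in 13 of 19 and lower in 1, as adjusted over the list alone (camera, adjusted p = 2.4e-05; adjusted p = 0.0207 with an estimated correlation), DUSP6 by 1.25. NRF2 antioxidant genes were higher with miR-1272 in 14 of 21, as adjusted over the list alone (camera, adjusted p = 1.57e-07; adjusted p = 0.00139 with an estimated correlation), AKR1C3, a near-identical copy of its relatives, by 1.43. With miR-141 they were lower in 14 of 21 and higher in 1, as adjusted over the list alone (camera, adjusted p = 2.35e-06; adjusted p = 0.00462 with an estimated correlation), HMOX1 by -1.19.

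NF-kB and inflammatory cytokine genes were lower with miR-875-5p than with the other mimics in 13 of 20 and higher in 2, as adjusted over the list alone (camera, adjusted p = 1.46e-05; adjusted p = 0.0331 with an estimated correlation). IL32 differed by -1.59 and IL6 by 2.45 (SE 0.19, limma adjusted p = 6.17e-08). Interferon-stimulated genes were lower with miR-221* in 17 of 29 and higher in 1 (19 and 1 adjusted over the list alone; camera, adjusted p = 1.09e-06; adjusted p = 0.0582 with an estimated correlation), IFIT2 by -1.26. G1/S and DNA replication genes were higher with miR-205* in 19 of 36 (24 adjusted over the list alone; camera, adjusted p = 8.89e-10; adjusted p = 0.0507 with an estimated correlation), MCM4 by 0.65. The 2 lists that kept their call with an estimated correlation for miR-205* against mock lost it here: histone genes were lower in 4 of 13 and higher in 1 (6 and 1 adjusted over the list alone; camera, adjusted p = 0.0195; adjusted p = 0.231 with an estimated correlation), with a mean of -0.19 against -0.60 against mock, and NRF2 antioxidant genes in 4 of 21, as adjusted over the list alone (camera, adjusted p = 0.044; adjusted p = 0.128 with an estimated correlation).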
